A study of Populus ussuriensis with 8 samples.

How the data were processed

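RNA was sequenced from the basal ends of stem cuttings of Populus ussuriensis, a poplar, in 8 libraries. The libraries form 4 groups of 2. Cuttings were kept without treatment or with 1 µM methyl jasmonate (MeJA, the methyl ester of the plant hormone jasmonic acid) and were harvested 0.5 h or 1 h after cutting. Groups and replicate numbers were taken from the submitters' sample labels. The growth and treatment texts in those labels give different ages for the source plants, and nothing in them says whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

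For each library the authors deposited 1 table of values per transcript, with poplar Potri identifiers that carry an isoform number. The unit is given neither in the file headers nor per the labels. It was taken to be FPKM, fragments scaled by transcript length and library size, as deposited by the authors. This reading rests on the values, which are not whole, are not on a log scale and sum to between 549538 and 577002 per library over the transcripts listed. HISAT2 2.1.0 and Bowtie2 2.2.3 are named in the submitters' processing notes. Their roles, the quantification tool, the genome build, the annotation and the use of strand are not given in the sources used here. Each table holds 65535 transcripts of 36385 genes below its header line and ends within the identifiers of chromosome 17. Later identifiers were not analysed here.

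Read counts were not used here, so absolute depth is unknown and no counting intervals are given. Relative depth was read from single-isoform genes under 1 FPKM, whose values are multiples of what 1 read is worth. Against untreated 0.5 h replicate 1, the most frequent ratio of these values placed the other 7 libraries at 0.931 to 1 times its depth. Between 10.9% and 12.5% of the ratios lay within 0.01 (log2) of that mode. A window of the same width 0.2 away held 0.478% to 0.932%. Libraries therefore differed little in depth.

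The FPKM of a gene was computed as the sum over its transcripts, a choice made once the files were seen to list transcripts. Genes with at least 1 FPKM in at least 2 libraries were tested, which left 24347 genes. Values were transformed as log2(FPKM + 1) with no further scaling. Fold changes called log2 below are on this scale, which understates the change of genes with low values. The 4 group means were fitted in limma 3.58.1 (R 4.3.3) with a variance trend and robust moderation, and contrasts gave the MeJA difference at each time, the time difference in each treatment and their interaction. An additive model gave the MeJA effect over both times and the time effect over both treatments. P-values were adjusted by the Benjamini-Hochberg method within a contrast and called at 0.05. A count test had been planned for files of read counts. As the files hold normalized values, the limma test planned for that case was used.

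The files do not pair the identifiers with gene names or descriptions, and no such table was used here. For that reason 31 planned gene lists (jasmonate, auxin, ethylene, cell wall and cell type markers among others), which were defined by gene descriptions, were not run. No gene is given a function here. By a rule fixed before the data were examined for identifiers without names, the text names 2 genes per direction for each contrast of the group means. It names none for the additive model. For the time contrasts these are the largest changes among called genes with a mean of at least 1 FPKM and no overlap between the groups. For contrasts without calls the rule asked for the 5 genes of smallest p. These were limited to 2 per direction, among genes with a mean of at least 1 FPKM, and are given as values. Chromosome numbers are those written in the identifiers. Paralogs, overlapping genes and antisense genes could share reads, and this was not resolved.

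The procedure was tested on simulated data, with 24347 genes at the real levels, spreads drawn from the fitted prior and 200 genes of at least 5 FPKM changed. For the MeJA contrast at 0.5 h, 72% of 2-fold and 97% of 4-fold changes were recovered with 8 unchanged genes called. For the time contrast without MeJA, 70% and 99% were recovered with 8 unchanged genes called. An earlier simulation, with each gene given its own estimated spread, called more unchanged genes than the threshold allows and was replaced by this one. An isoform test on simulated shares recovered 92% of shifts of 1 unit of log2 odds, with 10 unchanged isoforms called of 24868. In the simulations kept, noise was normal and independent between genes or isoforms, with spreads drawn as the test assumes. They therefore do not show how often unchanged genes are called in the real data. The real time contrast without MeJA also called 11830 genes, far more than the 200 changed here. Alternatives were quantile normalization, other filters, a pseudocount of 0.1, a fold threshold, a replicate block, fits of the compared libraries alone and leaving out each library. Median centring, transcripts in place of genes, a crossed replicate block and a plain variance prior were added after seeing the data. Figures were drawn with matplotlib 3.10.9.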

Results

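The transcriptome at the base of poplar stem cuttings, the site where adventitious roots later form, was measured at 2 early times after cutting, with and without MeJA. Each of the 4 groups (untreated 0.5 h, untreated 1 h, MeJA 0.5 h and MeJA 1 h) held 2 libraries. Between 22555 and 23236 genes per library reached 1 FPKM. Libraries of the same group had Spearman correlations of 0.983 to 0.987 across genes. Libraries of the same time but different treatment correlated at 0.981 to 0.986. Libraries of different times correlated at 0.892 to 0.924. The first principal component held 79.3% of the variance and separated the 4 libraries of 0.5 h from the 4 of 1 h. No library taken before cutting was analysed here, so each change below is between 0.5 h and 1 h or between treatments. Batches of harvest, extraction or sequencing were not known here. A batch shared by the libraries of 1 time could therefore not be told apart from the time after cutting.

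**Figure D1:**
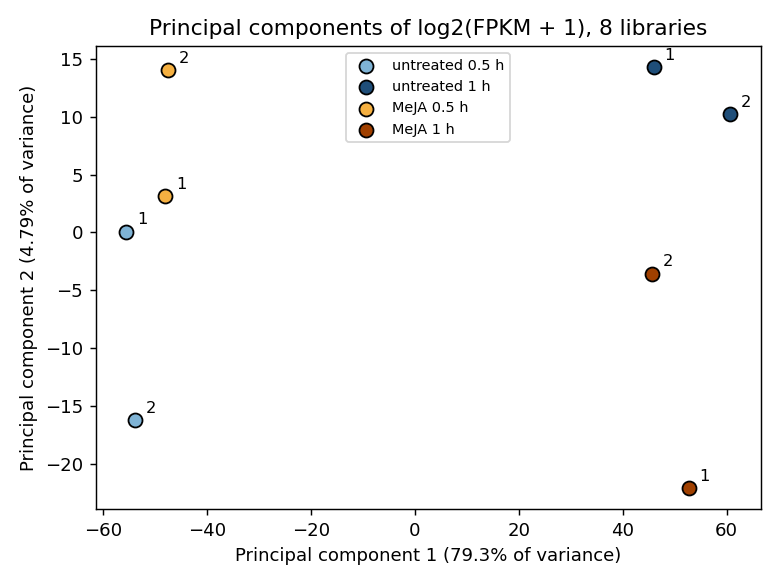
Principal components of log2(FPKM + 1) over the 24347 tested genes, with component 1 on the x axis and component 2 on the y axis (unitless scores). Each point is 1 library, coloured by group and numbered by replicate. The 0.5 h libraries lie between -55.6 and -47.5 on component 1 and the 1 h libraries between 45.7 and 60.7.

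The first comparison asked how transcript levels moved between 0.5 h and 1 h after cutting in untreated cuttings. Of 24347 genes, 11830 changed, 3749 of them upward and 8081 downward. On the log2(FPKM + 1) scale, which compresses falls to values near 0, 57 genes rose and 7 fell by at least 3. Potri.008G086700, on chromosome 8, rose from 3.63 ± 0.19 to 195 ± 52 FPKM (SD, n = 2), a log2 change of 5.38 ± 0.18 (SE; limma adjusted p = 2.8e-07). Potri.011G089700, on chromosome 11, rose from 0.38 ± 0.19 to 47.8 ± 16 FPKM, a log2 change of 5.11 ± 0.21 (limma adjusted p = 7e-07). Potri.015G101500, on chromosome 15, fell from 18.1 ± 9.3 to 0.181 ± 0.18 FPKM, a log2 change of -3.93 ± 0.39 (limma adjusted p = 0.00012). The level of this gene also differed between replicates at 0.5 h, at 24.7 and 11.5 FPKM. Potri.001G066400, on chromosome 1, whose neighbours by identifier changed in isoform shares, fell from 74.6 ± 22 to 4.51 ± 1.4 FPKM, a log2 change of -3.77 ± 0.22 (limma adjusted p = 2.9e-06). Rising genes made up 31.7% of the calls as deposited. The median gene moved by -0.19 (log2), and the share that rose was 47.5% after quantile normalization and 55.2% after each library was centred on its median. Both of these scalings even out the libraries by construction, so the shares do not show which balance of rising and falling genes is right.

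In MeJA-treated cuttings the same interval changed 10546 genes, 3706 upward and 6840 downward. Potri.008G086700 rose from 3.69 ± 0.71 to 169 ± 18 FPKM (SD, n = 2), a log2 change of 5.18 ± 0.18 (SE; limma adjusted p = 5.9e-07). Potri.006G101100, on chromosome 6, rose from 1.18 ± 0.046 to 63 ± 8.5 FPKM, a log2 change of 4.87 ± 0.2 (limma adjusted p = 9.8e-07). Potri.001G092900, on chromosome 1, fell from 124 ± 0.24 to 8.11 ± 1.3 FPKM, a log2 change of -3.79 ± 0.17 (limma adjusted p = 1.6e-06). Potri.015G101500 fell from 14.3 ± 7.4 to 0.395 ± 0.11 FPKM, a log2 change of -3.37 ± 0.39 (limma adjusted p = 0.00037). Rising genes made up 35.1% of these calls as deposited, 47.4% after quantile normalization and 53.4% after median centring. The median gene moved by -0.15 (log2).

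The log2 changes over time with and without MeJA rest on separate libraries and could be compared gene by gene. The calls share 1 estimate of spread per gene from all 8 libraries, so the lists of calls are not fully independent. Of the called genes, 2938 rose in both treatments, where independent lists of the same lengths would share 571. A further 5627 fell in both, against 2270 for independent lists. Opposite calls were made for 11 genes. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.894 and a Spearman correlation of 0.846. Their spread with MeJA was 0.916 times that without.

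**Figure D2:**
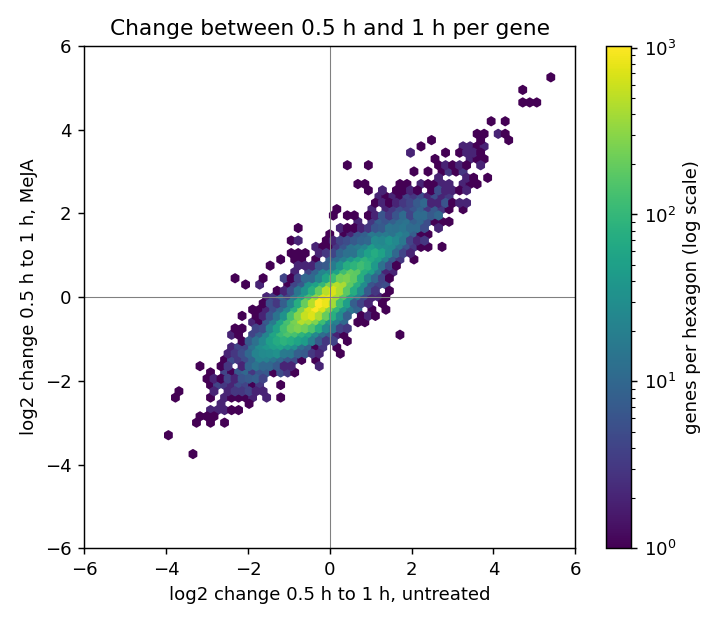
Log2 change from 0.5 h to 1 h per gene in untreated (x axis) and MeJA-treated cuttings (y axis), on the log2(FPKM + 1) scale. Colour gives the number of genes per hexagon on a log scale. Genes lie along the diagonal (Pearson correlation 0.894), and on this scale, which compresses falls to values near 0, the longest tail is toward rises in both treatments.

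Over both treatments, with 4 libraries at each time, 14651 genes changed between 0.5 h and 1 h as deposited, 4701 upward and 9950 downward. After median centring 6905 rose and 6299 fell, and after quantile normalization 6076 rose and 7321 fell. As deposited, the median rise was 0.61 and the median fall -0.54 on the log2 scale. Under 1 FPKM in the 4 libraries of 0.5 h and at 10 FPKM or more in the 4 of 1 h were 7 genes, and no gene (0) showed the reverse. Single-isoform genes rose in 21.6% and fell in 35.9% of 12431 cases. Genes with 4 or more isoforms rose in 15.5% and fell in 49% of 3756 cases. After quantile normalization, single-isoform genes rose slightly more often than they fell (27.3% and 26.5%), while genes with 4 or more isoforms still fell more often (20.9% and 37.4%). Of the 247 genes that rose by at least 2 on the log2 scale, 185 had a single isoform. Among genes over 50 FPKM, 28.6% rose and 33.3% fell, and among genes of 2 to 5 FPKM 14.2% rose and 43.6% fell. Under 2 FPKM 13.6% rose and 29.5% fell. After quantile normalization falls were less frequent at 2 to 5 FPKM (28%) than over 50 FPKM (34.9%), the reverse of the order as deposited, and rises were at 21.4% and 28.4%. Calls were spread over the 17 chromosomes listed, the last of them in part because the list ends within it, with 16.1% of genes rising on chromosome 13 and 23.6% on chromosome 11 as the extremes. These classes were chosen after seeing the data, and the differences between them were not tested.

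The next comparison asked which transcripts MeJA altered 0.5 h after cutting. No gene (0 of 24347) passed an adjusted p of 0.05 in limma, and 1899 genes (7.8%) had an unadjusted p under 0.05, 843 higher and 1056 lower with MeJA. The groups did not overlap for 36.5% of genes, where chance gives 33.3%. The genes with the smallest p were as follows. Potri.002G208400, on chromosome 2, stood at 31.3 ± 1.9 FPKM with MeJA and 17.8 ± 1.2 without (SD, n = 2; limma adjusted p = 0.16). Potri.014G022200, on chromosome 14, stood at 13.5 ± 2.1 FPKM with MeJA and 4.24 ± 0.87 without, a log2 difference of 1.47 ± 0.19 (SE; limma adjusted p = 0.16). Potri.003G038500, on chromosome 3, stood at 76.7 ± 7.4 FPKM with MeJA and 141 ± 11 without (limma adjusted p = 0.16). In untreated cuttings that gene was at 25 ± 1.3 FPKM by 1 h. Potri.001G074700, on chromosome 1, stood at 8.05 ± 1.6 FPKM with MeJA and 16.2 ± 0.067 without (limma adjusted p = 0.16). For 96.4% of genes the 95% confidence interval of the log2 difference lay within a 2-fold change in either direction on the log2(FPKM + 1) scale. Leaving out 1 library at a time gave 1 called gene without untreated 0.5 h replicate 1, untreated 0.5 h replicate 2 or MeJA 0.5 h replicate 1, and 0 otherwise.

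**Figure D3:**
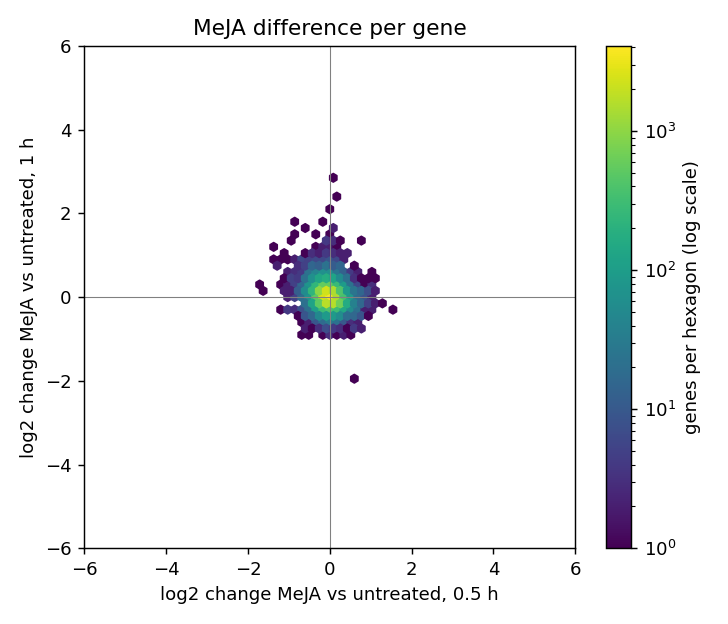
Log2 difference between MeJA and untreated cuttings per gene at 0.5 h (x axis) and 1 h (y axis), on the log2(FPKM + 1) scale and on the same axis range as the plot of the time response. Colour gives the number of genes per hexagon on a log scale. Most genes lie near 0, and the Pearson correlation is -0.183 (-0.222 to -0.0807 when each library was left out in turn).

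At 1 h, no gene (0 of 24347) differed between MeJA-treated and untreated cuttings at an adjusted p of 0.05 in limma, and 1444 genes (5.93%) had an unadjusted p under 0.05, 955 higher and 489 lower with MeJA. The groups did not overlap for 36% of genes, where chance gives 33.3%. Potri.012G064900, on chromosome 12, stood at 9.08 ± 1.3 FPKM with MeJA and 3.62 ± 0.54 without (SD, n = 2; limma adjusted p = 0.28). It stood at 10.1 ± 0.55 FPKM with MeJA and 10 ± 1.1 without at 0.5 h. Potri.001G084000 stood at 41.6 ± 2.2 FPKM with MeJA and 25.1 ± 0.17 without (limma adjusted p = 0.28). Potri.013G097700, on chromosome 13, stood at 11.6 ± 0.98 FPKM with MeJA and 17.4 ± 0.27 without (limma adjusted p = 0.5). Potri.013G101200 stood at 2.64 ± 0.15 FPKM with MeJA and 5.45 ± 0.37 without (limma adjusted p = 0.5). For 96.5% of genes the 95% confidence interval lay within a 2-fold change on the log2(FPKM + 1) scale. That scale understates the changes of genes with low values, and 8943 tested genes have a mean under 5 FPKM. The count depended on 1 library, as seen when each was left out. Without MeJA 1 h replicate 2, 46 genes were called higher with MeJA from replicate 1 alone, and in replicate 2 those genes had a median log2 difference from untreated of -0.09, against 1.86 in replicate 1.

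**Figure D4:**
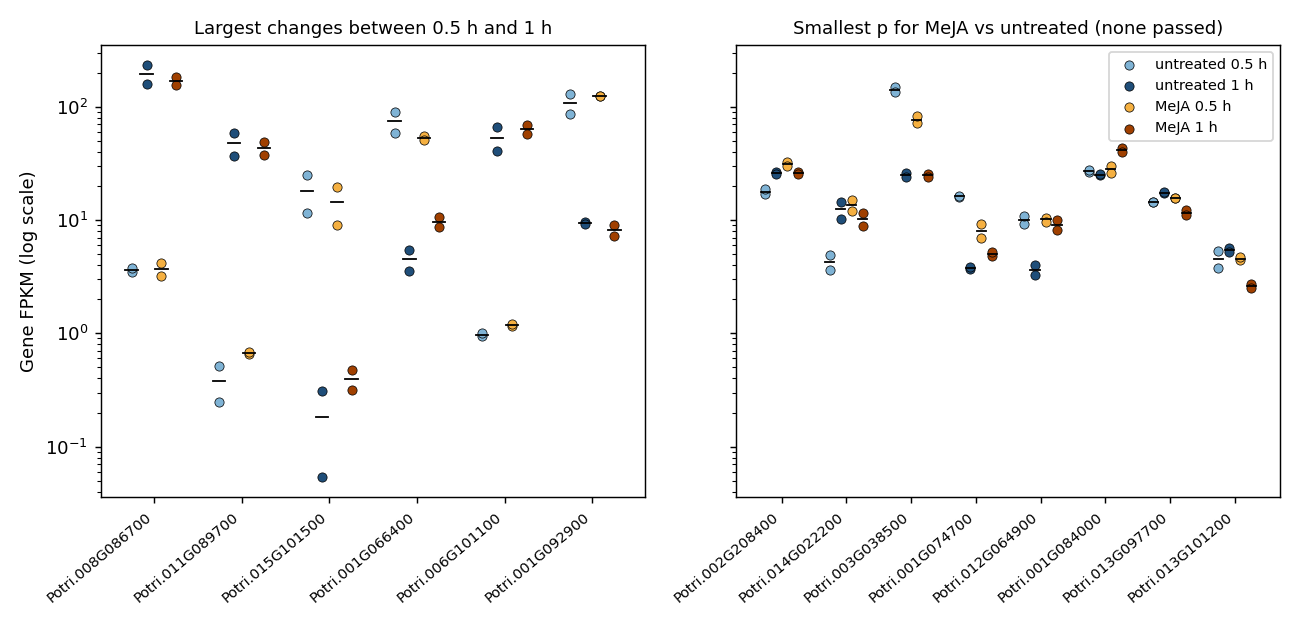
FPKM on a log y axis for the named genes (x axis) in the 8 libraries. Points are libraries coloured by group and bars are group means of 2 libraries. Genes on the left differ between times in both treatments, such as Potri.008G086700 (3.63 to 195 FPKM untreated). Genes on the right had the smallest p for MeJA and did not pass adjustment.

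Whether MeJA altered the change between the times was tested as an interaction. No gene (0) passed in limma and 2268 (9.32%) had an unadjusted p under 0.05. Without MeJA 1 h replicate 2, 9 genes were called, and 1 gene was called without untreated 0.5 h replicate 1 or without MeJA 0.5 h replicate 1. Potri.001G167600 stood at 10.8 ± 0.71 FPKM at 0.5 h and 3.31 ± 0.34 at 1 h without MeJA, and at 7.58 ± 0.32 and 6.34 ± 0.38 with it (SD, n = 2; limma adjusted p = 0.22). Potri.015G087700 stood at 66.5 ± 2.9 and 13.1 ± 2.7 FPKM without MeJA and at 41.5 ± 7 and 23.4 ± 2 with it (limma adjusted p = 0.22). Potri.014G022200 stood at 4.24 ± 0.87 and 12.4 ± 3 FPKM without MeJA and 13.5 ± 2.1 and 10.2 ± 1.9 with it (limma adjusted p = 0.22). Potri.009G010200 stood at 58.7 ± 4.8 and 145 ± 11 FPKM without MeJA and 86.2 ± 6.5 and 108 ± 0.99 with it (limma adjusted p = 0.22). The MeJA differences at 0.5 h and 1 h, which share no library, had a Pearson correlation of -0.183 and a Spearman correlation of -0.176 across genes. The Pearson correlation ranged from -0.222 to -0.0807 when each library was left out in turn. The MeJA differences had the same sign in 43.6% of genes. Over both times together, with 4 libraries per treatment, no gene (0) passed in limma and 890 (3.66%) had an unadjusted p under 0.05.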

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

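Median centring, transcripts in place of genes, a crossed replicate block and a plain variance prior were chosen after seeing the data. Counts of time-responsive genes stayed within 1.5 times of the reported ones except under 2 settings, where the cause is the setting's own construction. Requiring an absolute log2 change of 1 left 3078 genes without MeJA, 2379 with MeJA and 2536 over both treatments, and testing 47164 transcripts gave 20126, 17146 and 26069. The share of calls that rose was 47.5%, 47.4% and 45.4% after quantile normalization, 41.9%, 50.7% and 47.5% with the fold threshold, and 55.2%, 53.4% and 52.3% after median centring, in the same order. Leaving out each library in turn gave 7890 to 11526 genes without MeJA, 7272 to 10863 with MeJA and 12982 to 13796 over both, with 31.5% to 33.3%, 34.9% to 38% and 31.6% to 33% rising. For MeJA against untreated the leave-one-out counts were 0 to 1 at 0.5 h, 0 to 46 at 1 h, 0 to 9 for the interaction and 0 to 0 over both times. The highest values at 1 h and for the interaction came without MeJA 1 h replicate 2, where the remaining MeJA library is assumed to vary like the other groups. Transcripts gave 2 calls for MeJA at 0.5 h. The other alternatives run gave 0 calls for each of the 4 MeJA tests. The correlation of the MeJA differences at 0.5 h and 1 h was -0.222 to -0.0807 when each library was left out and -0.196 to -0.139 under the other alternatives. The named genes kept their direction and side of the threshold in 356 of 356 tries. In many tries the log2 change could not move, as when a library outside the contrast was left out. The genes were also picked as extremes, and for the MeJA and interaction contrasts the side kept was that of genes not called. The count is therefore not a measure of stability.

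Replicate numbers 1 and 2 recur in each group but did not pair the libraries: the correlations of same-numbered deviations were -0.12 to 0.033. With the replicate block 11465, 10132 and 14333 genes changed over time (untreated, MeJA, both), and 0 for MeJA at either time. With the numbers of the MeJA 1 h libraries crossed, the paired fit gave 11879, 10592 and 14541. DESeq2, voom and DESeq2 size factors were not run, since the files hold no counts. The gene list tests were not run without gene descriptions, and the correlation over genes called in either MeJA contrast was not run because no gene was called. Absolute depth is unknown, so what it limits was not measured. Recovery was simulated for genes of at least 5 FPKM, and 8943 tested genes have a lower mean.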

Other observations

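The isoform, transcript, scaling, displacement, neighbour and split tests below were chosen after the results they bear on had been seen. Among 24868 isoforms of 7694 genes with at least 5 FPKM in each library and a mean share of 10% to 90%, the share changed between 0.5 h and 1 h for 26 isoforms of 19 genes (limma on log2 odds, adjusted p under 0.05, both treatments). A pseudocount of 0.1 in place of 0.5 gave 19. The largest changes, chosen after their values were seen, were in Potri.005G056500, whose isoform 1 went from 82.2% ± 3.3 to 50.9% ± 4 of the gene (SD, n = 4; limma adjusted p = 0.00071), and in Potri.001G066600, whose isoform 2 went from 13.6% ± 2.5 to 40.8% ± 1.6 (limma adjusted p = 0.00034). Potri.001G066500, the next identifier on chromosome 1, also shifted, with isoform 1 at 46.1% ± 2 and then 67.3% ± 2.5 (limma adjusted p = 0.00071), and Potri.001G066400 beside it fell. Shares of isoforms are estimates, and reads shared between these neighbours were not resolved. For MeJA, no share (0) passed over both times and 1258 (5.06%) had an unadjusted p under 0.05. Shares were not tested for MeJA at 0.5 h or 1 h alone, so a change at 1 time only could be missed.

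When transcripts were tested in place of genes, 2 of 47164 differed between MeJA and untreated cuttings at 0.5 h, and both belonged to Potri.017G120300. Isoform 11 stood at 3.94 and 5.18 FPKM with MeJA and at 0.394 and 0.378 without (log2 difference 2.0 ± 0.16 SE, limma adjusted p = 0.0051). Isoform 1 stood at 0.602 and 0.237 FPKM with MeJA and at 3.97 and 4.53 without (log2 difference -1.9 ± 0.16 SE, limma adjusted p = 0.0051). The pair was named after its values were seen, and at 1 h isoform 11 stood at 0.151 to 0.561 FPKM and isoform 1 at 0.131 to 0.183. The 2 isoforms moved in opposite directions between similar low levels, so the 2 calls are not separate events. Isoform levels are estimates, and whether the same reads were assigned to the other isoform was not resolved.

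More genes fell than rose between 0.5 h and 1 h as the values were deposited. The median gene dropped by 11.4%, read from log2(FPKM + 1), which understates the drop in FPKM. A bound of 5.7% for the part due to abundant genes was set after the data were seen. The 100 most abundant genes held 15.9% of the signal at 0.5 h and 17.4% at 1 h. This larger share would lower the other genes by 1.8%, and by 4.73% between the most extreme libraries. Both values lie under the bound, which argues against those genes as the whole source. The 1000 most abundant genes went from 42.4% to 45.6%. That would lower the others by 5.59% and, between the most extreme libraries, by 9.74%. As these values lie on both sides of the bound, the larger share of the 1000 genes cannot be told apart from a lower level of the other genes. The scaling of whole libraries cannot be told apart from a lower level of most transcripts, because centring sets the median by construction and alone moved the share of rising calls to 52.3%. A real drop of most transcripts between the times stays open and was not tested.

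On the first principal component, MeJA libraries at 0.5 h lay toward the 1 h libraries, at 6.15% and 6.67% of the way from the untreated 0.5 h mean to the untreated 1 h mean. Noise of libraries that enter both contrasts predicts a correlation near 0 where no library is shared. In 4 pairings of disjoint libraries the MeJA difference and the time change correlated at 0.105 to 0.159 across genes (SD 0.0277). These pairings are not independent of each other, so their SD is not the spread that noise would give. A bound of 2 SD above 0, which the lowest value passed, replaced one of 0.1. Both bounds were set after values and other scalings had been seen, so no conclusion is drawn from them. Variation between cuttings, such as in the moment of harvest, cannot be told apart from an effect of MeJA: replicates lay 0.52% and 1.54% apart within the 0.5 h groups but 13.8% apart in untreated 1 h and 6.5% in MeJA 1 h. At 1 h the correlation over pairings of disjoint libraries ranged from -0.344 to 0.126. The 1 h replicates lay further apart on the axis, so this range does not measure the spread at 0.5 h. Whether the values at 0.5 h exceed the variation between cuttings was therefore not settled.

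Neighbouring genes changed alike between 0.5 h and 1 h. The Spearman correlation of log2 changes was 0.187 over 17122 pairs with consecutive identifiers, 0.0856 at a distance of 2 genes and 0.0413 at 5 (permutation p = 0.001 each, the smallest that 1000 permutations within chromosomes can give), and 0.0115 at 10 (permutation p = 0.17) and 0.0212 at 20 (permutation p = 0.007). At 5 genes the highest permuted value was 0.029, so reads shared between directly adjacent genes alone do not account for the whole pattern. Reads shared within arrays of similar genes cannot be told apart from joint regulation, which was not tested, because no sequences were used here. The longest run of consecutive genes that rose by at least 1 (log2) had 6 genes on chromosome 2 and the next 5 on chromosome 10, against at most 5 in 200 permutations, while the longest falling runs had 4 genes, also against at most 5.

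Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real split by time, gave as many as 14651 called genes, and the highest other split gave 0, with the time difference left in the residual of those splits. That residual keeps the calls of the other splits low in advance, so the comparison does not exclude chance. A lead in 1 of 35 splits also counts only if the libraries are independent, which the labels do not say. For MeJA over both times the real split gave 0 calls, a count that each of the 35 splits reaches by construction, so this comparison says nothing about chance. Among those 35, the split by time gave 14862 in a fit with no treatment term (14651 with one). The other splits in that set were fitted with time as a term, so the models differ and no conclusion is drawn from this count. At an unadjusted p under 0.05 the real MeJA split over both times had 890 genes, and 26 of the 33 splits other than it and the split by time had more, up to 2329. The split with 2329 set untreated 0.5 h and MeJA 1 h against the other groups, which is the interaction. Other splits can also carry part of a MeJA difference that depends on time. These counts therefore do not measure chance, and no conclusion is drawn from them. Within a time there are only 3 splits, too few for a share under 0.05. At 0.5 h the real one had 1899 genes at an unadjusted p under 0.05 and the highest other 1331, and at 1 h 1444 and 1194. The other splits within a time mix treated and untreated libraries in each group, so a MeJA difference would enter their residual. That would lower their counts in advance, and no conclusion is drawn from the lead of the real split. Each deposited table has 65536 lines, header included, and stops within chromosome 17. That number equals the row limit of an older spreadsheet format, and whether the list was shortened there was not tested.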
